A study of Mus musculus with 12 samples.

How the data were processed

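RNA from the proximal and distal ascending aorta of 6 mice was sequenced as 12 libraries. The mice were 2 months old, and 3 were wildtype and 3 heterozygous for a Notch1 allele on the strain the labels call Notch1.129S6+/-. Per the labels' protocols, RNA was extracted with Trizol and a column kit, treated with DNase, and 10 ng of total RNA was amplified to cDNA with the NuGEN Ovation RNA-Seq System v2. That kit does not mark the strand of the RNA, so reads from a gene and from an overlapping gene on the other strand cannot be told apart. The cDNA was fragmented enzymatically and sequenced on a HiSeq2500 with paired reads of 50 bases.

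Reads were aligned to the mouse genome mm10 with TopHat2 2.1.0 and Bowtie2, and R 3.2.2 was used, per the submitters' processing notes. The counting tool and the annotation version were not given in the sources used here. The authors deposited 1 RPKM value (reads per kilobase of gene, scaled to library size) for each gene in each library, on a list the file headers call filtered. Per the file headers, a detection threshold of 10 reads per gene corresponded to an RPKM of 0.136 to 0.189 in a library, and a reliable quantification threshold of 50 reads per gene to 0.680 to 0.943. Values below 0.1578 RPKM, the mean of the 12 detection thresholds, had been replaced by that value, per the file headers and the values, and 9.78% of all values lay at this floor. A ratio against a group with libraries at the floor is therefore a lower bound. The authors' deposited table also held p-values and false discovery rates of a 2-way ANOVA and of Tukey comparisons, and the authors' fold changes, which equalled the ratio of mean RPKM within 1% for all 17908 genes given for wildtype. The authors' ANOVA p-values matched a 2-way ANOVA of log2 RPKM within 1% for 100% of the 17297 genes compared. A re-sorted copy of the same values and a correlation matrix, 24 columns of per-sample values together, were not used.

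The depth was read from the values. Total reads per library, as the authors deposited them, were 26518332 to 36742096. Each gene's RPKM values were whole multiples of the step that 1 read stands for, within a tolerance of 0.0001, for 20170 of 20218 genes with at least 6 values above the floor (99.8%). The search for such steps was tested on simulated values, where it found a step in 100% of genes made from whole reads and in 0% of genes made from values that were not whole. The denominators of the RPKM worked back in this way were 14476722 to 20017786 reads, and total reads were 1.83 times as large. Gene lengths worked back from the steps equalled the summed exon length of GENCODE M21, an annotation of the same build, within 1 base for 77.9% of genes. Reads from the mitochondrial genome made up 24.1% to 43.7% of the summed RPKM of a library. Intervals on read counts cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

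Libraries were grouped by the genotype and location that the labels give. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.5), with empirical Bayes moderation and a variance trend over mean expression. The 17297 genes with an RPKM of at least 1 in at least 3 of the 12 libraries entered 1 model with 4 group means. The fitted log2 changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, while folds given in the text are ratios of mean RPKM. The 6 contrasts were proximal against distal in wildtype, in the libraries labelled Notch1+/- and averaged over genotypes, the genotypes compared in proximal and in distal tissue, and the interaction. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The test of counts planned for raw counts did not apply, since the files hold RPKM. The limma-trend fit was tested on simulated values with 100 genes changed per fold among 17297. The changed genes were drawn from those with a mean log2 level equal to at least 2 RPKM, so the shares below do not cover lower genes. No mouse effect was simulated, so these values cannot show what a mouse block gains. A 2-fold change was called for 24% of genes for location in wildtype, 29% for location in the libraries labelled Notch1+/-, 56% for location averaged, 17% and 21% for genotype in proximal and distal tissue and 4% for the interaction. A 4-fold change was called for 89%, 86%, 93%, 88%, 81% and 47% in the same order, with 2 to 9 false calls per contrast. With the mouse as a block, which applies to location and interaction, a 2-fold change was called for 15%, 13%, 42% and 0%, and a 4-fold change for 84%, 80%, 94% and 18%, in the order wildtype, Notch1+/-, averaged and interaction.

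The choices above, 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Lists covered Notch signalling, contractile smooth muscle, elastic fibre, collagen and proteoglycan, matrix protease, TGF-beta and BMP, heritable aortopathy, renin-angiotensin, chondrogenic and valve, cardiac and second heart field, neural crest and Hox genes. Other lists held markers of heart muscle, skeletal muscle, endothelium, adventitial fibroblasts, white and brown fat, macrophages, lymphocytes, erythroid cells, nerve and glia, mesothelium and epithelium, and genes of early stress, inflammation, interferon response, proliferation and the mitochondrial genome. The 25 lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, beside the same test with an estimated correlation and limma's fry, with Benjamini-Hochberg adjustment over lists within a contrast. In simulated data camera called both raised lists and 0 of the other lists, under both kinds of correlation and in all 6 contrasts. The simulated genes varied independently of each other, while the estimated correlation of the real lists reached 0.960 for mitochondrially encoded genes. The simulation therefore cannot show false calls of lists whose members vary together. The named genes were the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 RPKM in the higher group and no overlap between the groups' libraries. Where fewer than 10 genes were called, the 5 smallest unadjusted p in each direction were named as not called, whether or not the groups overlapped. Both sets were limited to genes with an official symbol, so predicted models (Gm, Rik and LOC names) of larger change or smaller p were skipped. The code also skipped clone names, pseudogenes with a ps suffix, microRNAs, small nucleolar and 5S ribosomal RNAs and symbols held by several genes, which the fixed wording does not list. From each list the 4 members of smallest p could be named, and Notch1, Hes1, Hey1, Hey2, Heyl and Acta2 in every contrast. Genes outside this rule are named as chosen after their values were seen.

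The tissue identifiers in the files tie the proximal and the distal library of a replicate number within a genotype to 1 mouse, so these numbers pair the libraries. Deviations of such libraries from their group means correlated at 0.115, 0.130 and 0.216 in the mice labelled Notch1+/- and at 0.160, 0.0731 and 0.108 in wildtype. Between the genotypes, libraries of the same number and location correlated at 0.0167, 0.101 and 0.168 in distal and at 0.131, -0.0265 and 0.249 in proximal tissue. The fit with the mouse as a replicate block was an alternative to the main design. Across genotypes no identifier ties a shared number to an animal or a litter, but the library identifiers run in consecutive sets of 4 that hold 1 number each. For the genotype contrasts the replicate number was therefore the block. Other alternatives were 3 other scalings, pseudocounts of 0.1 and 1, no filter or a filter at 0.1 RPKM, only the libraries compared, no variance trend, array weights, and each library left out in turn. Chosen after the data were seen were limma-voom on the worked-back reads, scaling to protein-coding genes, protein-coding genes alone, a heart muscle score as a covariate, and the fit without the 2 distal libraries with the most heart muscle transcripts. Principal components and average-linkage clustering used log2(RPKM + 0.5) of the genes past the filter. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the read steps, annotation overlaps and plots.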

Results

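Gene expression was measured by RNA sequencing of the ascending aorta, divided into a proximal part next to the aortic root and a distal part, in mice heterozygous for Notch1 and in wildtype littermates. Notch1 encodes a receptor whose cleaved intracellular domain activates transcription of the Hes and Hey genes. The study asked why dilation of the aorta in the heterozygous mice was confined to the root. Each of the 4 groups of genotype and location held 3 libraries, 1 per mouse at 2 months of age. Total reads per library were 26518332 to 36742096, and 17297 genes passed the filter on low values. Separate mice stand behind the replicates of a group, while proximal and distal libraries come from the same mice. All 12 libraries held transcripts of the Y-linked gene Ddx3y, at 6.25 to 8.79 RPKM.

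Notch1, the gene the mice are named for, was higher in every library labelled Notch1+/- than in every wildtype library of the same location. In distal tissue its mean was 1.52 ± 0.34 RPKM (SD, n = 3) in the libraries labelled Notch1+/- and 0.877 ± 0.30 in wildtype (n = 3). In proximal tissue it was 1.83 ± 0.32 against 1.29 ± 0.24 RPKM (n = 3 each). The fitted log2 differences were 0.56 (SE 0.25) and 0.38 (SE 0.25), with limma adjusted p of 1 and 0.999. An exact 2-sided permutation test gave p = 0.1 at each location, the smallest that 3 against 3 libraries allow. These values rest on 133 to 488 reads per library. The direction goes against the genotype label for a gene present in 1 copy, so groups are written as libraries labelled Notch1+/-. Notch1 (ENSMUSG00000026923, mm10 chromosome 2, 26457903 to 26516663, minus strand) shares 9.76% of its exon bases with genes on the opposite strand. Which part of the gene the targeted allele lacks was not given in the sources used here. The Notch targets did not pass the test in either location. Their log2 differences in proximal tissue were 0.64 (SE 0.44) for Hes1, -0.13 (SE 0.31) for Hey1, 0.10 (SE 0.22) for Hey2 and 0.23 (SE 0.30) for Heyl. In distal tissue they were 0.15, -0.17, 0.20 and 0.41 with the same standard errors. Acta2, the smooth muscle actin of the aortic media, stood at 1620 ± 217 RPKM in wildtype proximal libraries and 2046 ± 284 RPKM in those labelled Notch1+/- (n = 3 each), a log2 difference of 0.34 (SE 0.21).

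**Figure D1:**
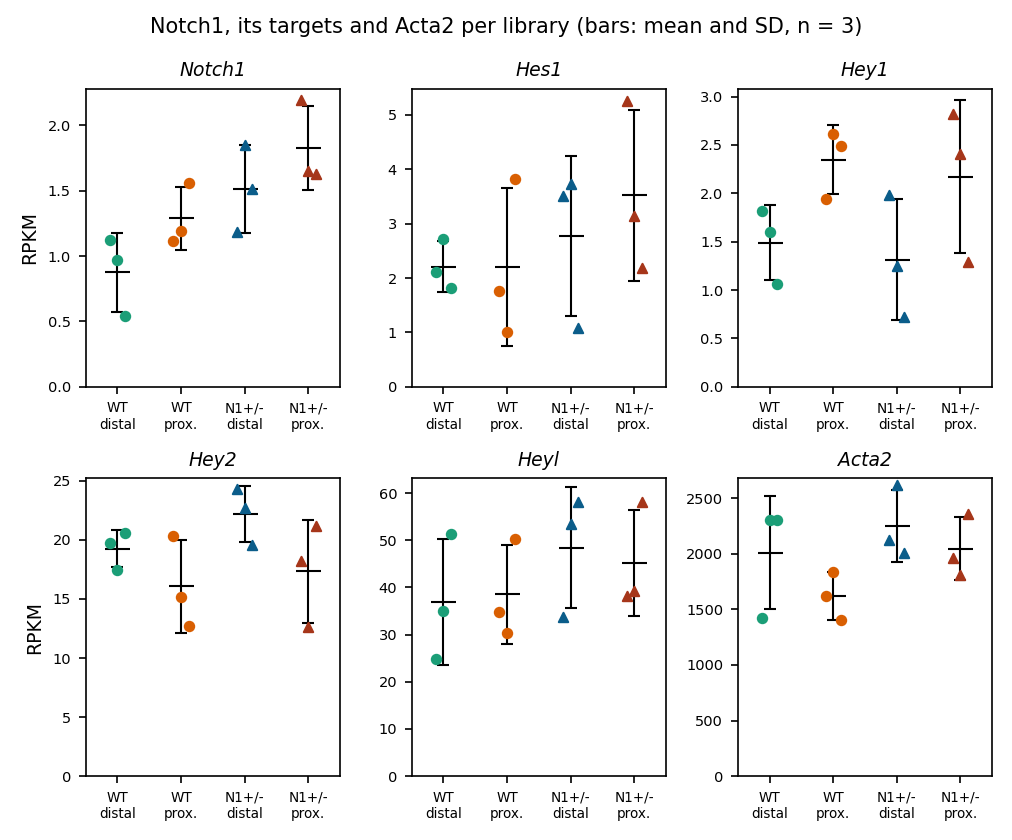
RPKM of Notch1, the Notch targets Hes1, Hey1, Hey2 and Heyl, and Acta2 on linear axes from 0, with 1 point per library in 4 groups and bars for mean and SD (n = 3). Notch1 lies higher in each library labelled Notch1+/- (N1+/-) than in each wildtype (WT) library of its location, while the targets and Acta2 overlap between genotypes.

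In wildtype mice the matrix genes Chad, Clec3a, Prg4 and Thbs4 and the cardiac transcription factor genes Gata4 and Tbx20 were among those higher in the proximal than in the distal ascending aorta. Ptn, the heparin-binding growth factor pleiotrophin, was 26.0-fold higher, at 14.5 ± 5.41 against 0.559 ± 0.142 RPKM (SD, n = 3 each; log2 3.77, SE 0.28, adjusted p 7.36e-05). Chad, a matrix protein of cartilage, reached 61.2 ± 33.8 against 4.53 ± 1.51 RPKM, a ratio of 13.5 (log2 3.48, SE 0.51, adjusted p 0.0155). Clec3a, a C-type lectin of cartilage, lay at the floor in all distal libraries and at 5.52 ± 1.07 RPKM in proximal libraries, at least 35.0-fold higher (log2 3.18, SE 0.20). Its distal values in both genotypes are that 1 replaced value (SD 0), so the SE does not measure distal spread. Spp1, which encodes osteopontin, was 22.1-fold higher, Igfbp3, which binds insulin-like growth factors, 13.2-fold, and Prg4, which encodes lubricin, 7.74-fold. The matrix protein Thbs4 was at least 23.9-fold higher, and Corin, the protease that activates atrial natriuretic peptide, 7.88-fold. The cardiac transcription factors Gata4 and Tbx20 were 9.01-fold and 5.73-fold higher, the latter at 22.3 ± 7.82 against 3.89 ± 0.81 RPKM. Among genes higher in distal tissue were 4 copies of the gene for alpha-1 antitrypsin, an inhibitor of neutrophil elastase. Serpina1b was at least 13.5-fold higher distally, at 6.63 ± 0.66 RPKM (log2 -2.99, SE 0.39, adjusted p 0.00975). Serpina1d was at least 10.2-fold, Serpina1a at least 8.16-fold and Serpina1c at least 7.85-fold higher distally. These paralogs share sequence, so the split of reads among them is uncertain, and Serpina1a and Serpina1c lost the call under 3 of 4 other scalings. Car8, an inactive relative of carbonic anhydrases, was 10.1-fold higher distally, and Vipr2, a receptor for vasoactive intestinal peptide, 11.5-fold. Vtcn1, an inhibitory ligand of T cells, was 4.38-fold and F3, the tissue factor that starts coagulation, 3.42-fold higher distally. The peptidase-like gene Cpxm2 and the proline transporter gene Slc6a7 were 3.47-fold and 2.87-fold higher.

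By list, wildtype proximal tissue was higher for 4 of 8 measured cardiac and second heart field factors and for 2 of 14 chondrogenic and valve genes. With adjustment over the list alone, 4 cardiac factors rose and 1 fell, and 6 chondrogenic genes rose. Both lists were called by camera, with adjusted p of 7.54e-07 and 2.11e-12, and adjusted p = 0.0407 for each with an estimated correlation. The 6 measured Hox genes, which specify position along the body axis, were lower in proximal tissue as a list at adjusted p 1.18e-10. That value was 0.00303 with an estimated correlation, and all 6 fell with adjustment over the list alone, although none of them passed over all genes. All 22 heart muscle markers were fitted higher in proximal tissue, 15 passed with adjustment over the list alone, and camera gave an adjusted p of 5.16e-25, or adjusted p = 0.0889 with an estimated correlation. Elastic fibre genes were lower as a list at 1.08e-06, with 5 lower when adjusted over the list alone, adventitial fibroblast markers at 0.00646 and mesothelial markers at 0.00153. Macrophage markers were higher at 2.86e-05, early stress genes at 0.0268, inflammatory genes at 0.00248 and mitochondrially encoded genes at 0.00047. Those 7 calls were lost with an estimated correlation, at adjusted p = 0.288 for elastic fibre, 0.316 for macrophage and 0.204 for inflammatory genes, 0.575 for early stress genes and 0.555 for the other 3. Of 9 inflammatory genes 5 were fitted higher and 4 lower, at a median log2 change of 0.08. Early stress genes also lost the call under 3 other scalings, and mitochondrially encoded genes under quantile normalization. Calls of lists lost when 1 library was left out were those of macrophage markers (adjusted p 0.116), inflammatory genes (0.0678) and early stress genes (0.748) without distal library 3, and of fibroblast markers without distal or proximal library 2 (0.101 and 0.106). Mesothelial markers lost the call without distal library 1 (0.0605) or proximal library 3 (0.129), mitochondrially encoded genes without proximal library 3 (0.0586), and early stress genes without proximal library 1 or 2 (0.114 and 0.201). The lists of Notch (median log2 change -0.13), TGF-beta (-0.13) and contractile genes (-0.02) had negative medians where camera, which ranks a list against the other genes, placed them higher, at adjusted p of 0.407, 0.620 and 0.372. Over all genes the median log2 change was -0.13, and -0.24 with RPKM rescaled to a constant sum.

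In all, limma called 20 genes higher and 21 lower among 17297, with 1429 genes at an unadjusted p under 0.05 where chance gives 865. The count fell to 21 (12 higher, 9 lower, 19 of them shared) with the mouse as a block, which ended the calls of Prg4, Gata4, Corin, Vipr2, Vtcn1, F3, Cpxm2 and Slc6a7, and to 2 with a heart muscle score as a covariate, which correlated with location at 0.833. With only the wildtype libraries in the model it was 5 (3 higher, 2 lower), and of the 20 named genes Ptn, Clec3a, Spp1 and Car8 kept the call. Without wildtype distal library 3 it was 7 and without distal library 1 it was 13, without proximal libraries 1, 2 and 3 it was 16, 17 and 19, and 6 of the 20 named genes (Ptn, Clec3a, Spp1, Prg4, Igfbp3 and Gata4) passed whichever library was left out, while each of the other 14 lost the call in at least 1 case.

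In the libraries labelled Notch1+/-, the cartilage matrix genes Chad, Prg4 and Comp and the striated muscle genes Lmod2, Tnnc1 and Ankrd1 were among those higher in the proximal than in the distal part. Chad stood at 74.5 ± 12.1 against 3.00 ± 1.90 RPKM, a ratio of 24.9 (SD, n = 3 each; log2 4.61, SE 0.51, adjusted p 0.00214). Spp1 was at least 69.5-fold and Clec3a at least 62.9-fold higher, the latter at 9.94 ± 1.22 RPKM. Ptn was at least 30.2-fold, Prg4 16.7-fold and Comp, a cartilage matrix protein gene, 15.2-fold higher. The thrombospondin gene Thbs1, whose product can activate TGF-beta, was 12.2-fold higher. Genes of the contractile apparatus and metabolism of striated muscle included Lmod2, at least 19.2-fold, Tnnc1, 12.2-fold, Ankrd1, 10.4-fold, and Pgam2, 14.0-fold. Pgam2 lost its call under median-of-ratios scaling. On the distal side, Car8 was 8.46-fold, Serpina1b 6.78-fold, Vtcn1 4.30-fold and F3 3.38-fold higher. Abcc9, a subunit of ATP-sensitive potassium channels, stood at 102 ± 9.09 RPKM distally against 43.7 ± 7.05 proximally, 2.34-fold higher.

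By list, proximal libraries labelled Notch1+/- were higher for 3 of 14 chondrogenic and valve genes and 4 of 8 cardiac and second heart field factors. With adjustment over the list alone these were 7 and 4. Camera gave adjusted p of 2.53e-12 and 4.37e-05, and adjusted p = 0.0621 and 0.0744 with an estimated correlation. The Hox list was lower at 2.22e-10, and at 0.00333 with an estimated correlation, with 0 of 6 genes called over all genes and 6 adjusted over the list alone. Heart muscle markers were fitted higher in 22 of 22 cases, with 1 called over all genes, 17 adjusted over the list alone, and an adjusted p of 1.92e-21 (adjusted p = 0.127 with an estimated correlation). Macrophage markers were higher at 1.31e-05, brown fat markers at 0.00933, endothelial markers at 0.0416 and inflammatory genes at 0.0088. Elastic fibre genes were lower at 0.00057, neural crest factors at 0.0173 and mesothelial markers at 0.000109. With an estimated correlation the adjusted p of these 7 was 0.306, 0.435, 0.702, 0.300, 0.435, 0.306 and 0.356 in that order. Of 9 inflammatory genes 6 were fitted higher and 3 lower, at a median log2 change of 0.06. Endothelial markers also lost the call with the mouse as a block, at adjusted p = 0.104. Leaving out 1 library ended the call of endothelial markers without distal library 1 (0.546), proximal library 1 (0.0529) or proximal library 2 (0.0832) labelled Notch1+/-, or wildtype proximal library 1 (0.0537). It ended that of neural crest factors without distal library 3 (0.108) or proximal library 3 (0.132) labelled Notch1+/-, and that of brown fat markers without distal library 2 (0.173). Collagen (median log2 change -0.05), protease (-0.04) and heritable aortopathy genes (-0.11) had positive means beside negative medians, and camera placed them lower at adjusted p of 0.888, 0.620 and 0.449.

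Limma called 37 genes higher and 7 lower, with 1240 genes at an unadjusted p under 0.05, and quantile normalization split 54 calls into 40 and 14. The mouse as a block ended the calls of Lmod2, Tnnc1, Serpina1b, Vtcn1 and Thbs1. The count was 3 with a heart muscle score as a covariate, and 321 with array weights. It was 17, 14 and 21 without proximal libraries 1, 2 and 3 labelled Notch1+/- and 21, 22 and 16 without the distal ones, and 7 of the 17 named genes called (Chad, Spp1, Clec3a, Ptn, Prg4, Ankrd1 and Thbs4) passed whichever library was left out.

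**Figure D2:**
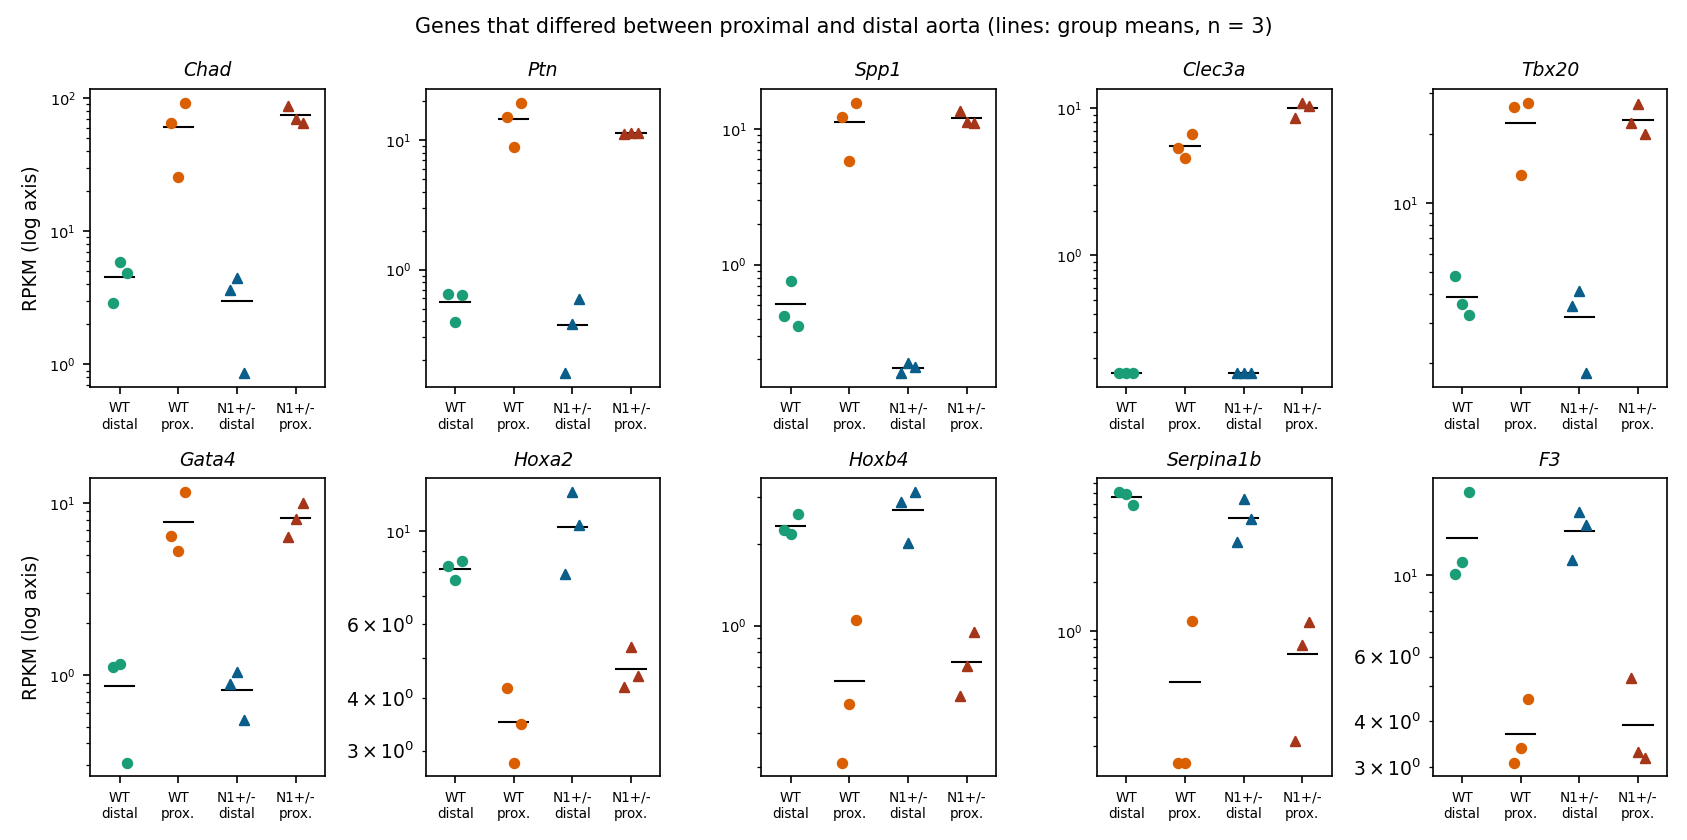
RPKM of 10 named genes on log axes, with 1 point per library and lines for group means (n = 3) in wildtype (WT) and in libraries labelled Notch1+/- (N1+/-). Chad, Ptn, Spp1, Clec3a, Tbx20 and Gata4 lie higher in proximal libraries, Hoxa2, Hoxb4, Serpina1b and F3 in distal ones, and points at 0.1578 RPKM are at the floor.

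Averaged over genotypes, 6 genes of cartilage and valves were higher in proximal tissue. Of 14 measured chondrogenic and valve genes 6 rose, 9 did so with adjustment over the list alone, and 0 fell. Chad was 18.0-fold higher, at 67.9 ± 23.9 against 3.76 ± 1.75 RPKM (SD, n = 6 each; log2 4.05, SE 0.36). Prg4 was 10.4-fold higher, Comp 9.32-fold, Hapln1, which links hyaluronan to proteoglycans, 5.68-fold, and Cilp2 at least 6.44-fold. Sox9, the transcription factor that directs cartilage formation, was at least 6.46-fold higher, at 3.82 ± 1.49 against 0.591 ± 0.381 RPKM. Camera gave this list an adjusted p of 1.89e-14, or 0.0393 with an estimated correlation. Outside the list, Spp1 was at least 34.2-fold, Ptn at least 27.7-fold and Clec3a at least 49.0-fold higher. Cilp2 lost its call with the mouse as a block.

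Called cardiac transcription factors and called Hox genes differed by location in opposite directions. Gata4 was 9.45-fold, Tbx20 6.43-fold, Tcf21 3.59-fold and Hand2 2.04-fold higher in proximal tissue (n = 6 each). Tbx20 (mm10 chromosome 9, 24720812 to 24774303) stood at 22.7 ± 5.46 against 3.53 ± 1.0 RPKM. These were 4 of 8 measured cardiac and second heart field factors, with 1 lower when adjusted over the list alone, and the list had an adjusted p of 4.81e-06 (adjusted p = 0.0466 with an estimated correlation). Of 6 measured Hox genes 5 fell, and all 6 did so with adjustment over the list alone. Hoxb4 (chromosome 11, 96318267 to 96321638) was 3.69-fold higher in distal tissue, at 2.51 ± 0.431 against 0.680 ± 0.279 RPKM. Hoxa2 (chromosome 6, 52162417 to 52164831) was 2.24-fold, Hoxb3 2.36-fold, Hoxa3 2.12-fold and Hoxa5 at least 3.61-fold higher distally, and Hoxa4 had a log2 difference of -1.10 at adjusted p 0.0672. The Hox list had an adjusted p of 4.28e-12, and 0.00189 with an estimated correlation. Reads of Hoxb3 are uncertain, since 52.9% of its exon bases overlap an antisense gene, as are those of Hoxa3, which shares 25.4% with a gene on the same strand, and of Hoxa4 and Hoxa2, which share a smaller part with it, and Hoxa5 lost its call with the mouse as a block. Neural crest factors were lower as a list at 0.0384 (adjusted p = 0.348 with an estimated correlation), with Dlx5, a homeobox gene of craniofacial neural crest, at least 4.90-fold higher distally. With adjustment over the list alone 1 of them rose and 3 fell, and the list lost its call with RPKM rescaled to a constant sum.

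Heart muscle genes stood higher in proximal tissue next to these groups. Of 22 measured cardiomyocyte markers 12 rose, 20 did so with adjustment over the list alone, and all 22 were fitted higher. Tnnt2, the cardiac troponin T gene, was 9.96-fold higher, at 82.5 ± 44.6 against 8.28 ± 11.0 RPKM (n = 6 each). Csrp3 was 12.3-fold, Lmod2 at least 10.4-fold, Tnnc1 7.02-fold, Actn2 4.37-fold and Pln, which regulates the calcium pump of the sarcoplasmic reticulum, 6.31-fold higher. Myh6, the atrial and adult mouse heart myosin, ranged from 63.2 to 354 RPKM in proximal libraries. Distally it stood at 119 RPKM in wildtype library 2, at 48.0 in library 1 labelled Notch1+/- and at 2.12 to 5.30 in the other 4. The list had an adjusted p of 3.98e-29, and adjusted p = 0.0611 with an estimated correlation. Reads of Pln are uncertain, since 64.7% of its exon bases overlap another gene. Without the pair of distal libraries with the most Myh6, 158 genes were called (103 higher, 55 lower), of which 137 were also among the 260. That fit still set proximal libraries with Myh6 at 63.2 to 354 RPKM against distal ones at 2.12 to 5.30. The overlap therefore cannot show whether heart muscle brought the calls.

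**Figure D3:**
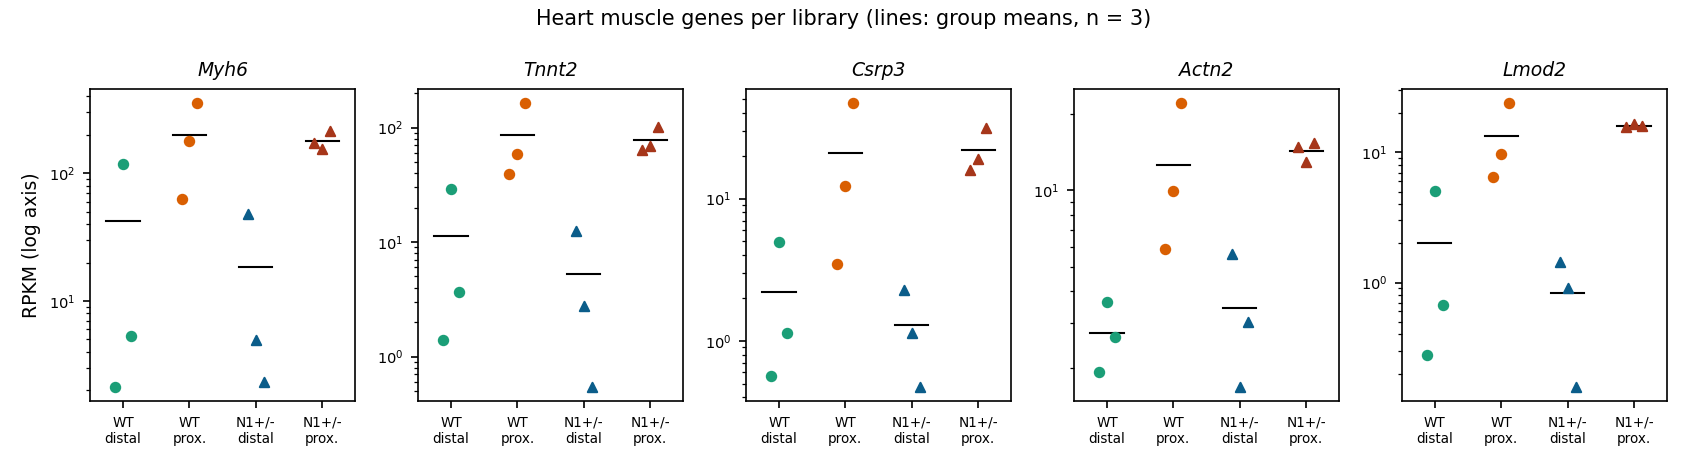
RPKM of 5 heart muscle genes on log axes, with 1 point per library and lines for group means (n = 3). Wildtype (WT) distal library 2 and distal library 1 labelled Notch1+/- (N1+/-) lie highest among distal libraries for Myh6, at 119 and 48.0 RPKM, the former above wildtype proximal library 1 at 63.2 RPKM.

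Genes of the vessel wall itself were divided. Of 20 elastic fibre genes 2 fell in proximal tissue, 7 with adjustment over the list alone: Efemp1, a fibulin gene, was 2.95-fold and Mfap5, a microfibril protein gene, 1.97-fold higher distally. That list was lower at 1.19e-06, and adjusted p = 0.249 with an estimated correlation. Of 27 collagen and proteoglycan genes Col8a1 was 4.41-fold higher in proximal tissue and Col15a1 1.75-fold higher in distal tissue, and 3 fell with adjustment over the list alone. Timp2, an inhibitor of matrix metalloproteinases, was 1.54-fold higher distally, the sole call among 18 protease genes, and lost its call with the mouse as a block. Thbs1 was 7.73-fold higher proximally, the sole call among 29 TGF-beta and BMP genes. Des, the muscle intermediate filament gene, was 2.90-fold higher proximally, at 73.6 ± 8.14 against 25.4 ± 7.23 RPKM, the sole call among 20 contractile genes. Mfap5 was the sole call among 23 heritable aortopathy genes, and 0 of 21 Notch genes and 0 of 5 renin-angiotensin genes passed. With adjustment over the list alone 1 Notch gene rose, 1 contractile gene rose and 1 fell, 2 protease genes rose and 2 fell, 2 TGF-beta genes rose and 1 fell, and 1 aortopathy gene rose and 2 fell. Notch3, the Notch receptor of smooth muscle, was 1.77-fold higher proximally at adjusted p 0.0625, and passed under 3 of 4 other scalings and with the mouse as a block. The adjusted p of these other lists were 0.403 for collagen, 0.144 for protease, 0.316 for TGF-beta, 0.459 for contractile, 0.121 for heritable aortopathy, 0.403 for Notch and 0.403 for renin-angiotensin genes.

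All 9 macrophage markers were fitted higher in proximal tissue and 6 rose with adjustment over the list alone, although none passed over all genes (list adjusted p 2.83e-07, adjusted p = 0.192 with an estimated correlation). Lyz2, the lysozyme gene of myeloid cells, had a log2 difference of 1.31 at adjusted p 0.0721 and passed under 3 of 4 other scalings. Inflammatory genes were higher at 0.00375 (adjusted p = 0.192 with an estimated correlation), with Spp1 and the chemokine gene Cxcl12 (log2 0.96) called. Of the 9 measured, 5 were fitted higher and 4 lower, at a median log2 change of 0.04, so the list as a whole was not shifted. Brown fat markers were higher at 0.00724 (adjusted p = 0.390 with an estimated correlation), where the calls were Cox7a1, a cytochrome oxidase subunit also used in heart, 5.47-fold higher, and Dio2, a thyroid hormone deiodinase, 5.46-fold higher distally. Mesothelial markers were lower at 2.79e-05 (adjusted p = 0.299 with an estimated correlation), with Gpm6a 2.06-fold higher distally. Fibroblast markers were lower at 0.0297 (adjusted p = 0.550 with an estimated correlation), with Pi16 2.09-fold higher distally. Among 17 endothelial markers Emcn was at least 6.10-fold higher proximally, while Pecam1 had a log2 difference of -0.75 at adjusted p 0.135 (list 0.0703). With adjustment over the list alone 5 endothelial and 5 brown fat markers rose and 3 and 2 fell, 4 inflammatory genes rose and 1 fell, and 3 mesothelial and 3 fibroblast markers fell. Early stress genes at 0.0407 and mitochondrially encoded genes at 0.0111 were higher, with adjusted p = 0.550 for each with an estimated correlation, and early stress genes lost the call under 3 other scalings and mitochondrially encoded genes under quantile normalization. Lists of white fat (0.0556), erythroid (0.143), neural and glial (0.171) and interferon genes (0.104) were not called, and skeletal muscle, lymphocyte, epithelial and proliferation lists had fewer than 3 measured members.

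Leaving out 1 library ended 5 of the averaged list calls. Neural crest factors lost it without distal library 3 (adjusted p 0.123) or proximal library 3 (0.0828) labelled Notch1+/-, wildtype distal library 1 (0.0887) or wildtype proximal libraries 2 and 3 (0.0885 and 0.0737). Fibroblast markers lost it without distal library 2 labelled Notch1+/- (0.0637), wildtype distal library 2 (0.106) or wildtype proximal library 2 (0.115), and brown fat markers without distal library 2 labelled Notch1+/- (0.0508). Mitochondrially encoded genes lost it without distal library 2 (0.760) or proximal library 3 (0.0713) labelled Notch1+/-, or wildtype proximal libraries 2 and 3 (0.0603 and 0.0938). Early stress genes lost it without distal libraries 2 and 3 (0.1003 and 0.123) or proximal library 1 (0.282) labelled Notch1+/-, wildtype distal library 3 (0.326) or wildtype proximal libraries 1 and 2 (0.0878 and 0.153). Elastic fibre, chondrogenic, cardiac, Hox and heart muscle lists passed whichever library was left out, in each genotype and on average.

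Over both genotypes limma called 134 genes higher and 126 lower in proximal tissue, 179 of them with a fitted change of at least 2-fold, and 1924 genes had an unadjusted p under 0.05. A heart muscle score as a covariate left 3 calls, while the median absolute log2 change of the 260 genes went from 1.18 to 0.98, with 252 of the same sign, and the median SE from 0.21 to 0.36. Array weights gave 445 calls. The count was 170 without distal library 2 labelled Notch1+/-, 173, 141 and 156 without proximal libraries 1, 2 and 3 of that label, and 160 and 171 without wildtype distal library 3 and wildtype proximal library 3. Of the 56 named genes called, 50 passed whichever library was left out, the exceptions being Cilp2, Hoxa5, Myh6, Col15a1, Gpm6a and Cox7a1.

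The location differences were compared between genotypes. Of the calls, 18 genes were higher and 6 lower in proximal tissue in both genotypes, where independent lists would share 0.0428 and 0.0085. The 24 shared genes included Clec3a, Spp1, Ptn, Chad, Prg4, Igfbp3, Thbs4, Gata4, Tbx20, Tcf21, Hand2, Des and Col8a1 as higher, and Serpina1b, Car8, Vtcn1, F3 and Abcc9 as lower. Of 41 wildtype calls 39 had the same sign in the libraries labelled Notch1+/-, as did 44 of 44 calls in the other direction. Across all 17297 genes, which are not independent, the location changes correlated at Pearson 0.460 and Spearman 0.305. The 2 contrasts share no library. They come from 1 model, though, and have the same standard error for each gene. A gene of small spread is therefore favoured in both lists, so the overlap of independent lists is not a test of chance. The interaction, which tests whether location differences depend on genotype, gave 0 calls with limma, 507 genes at an unadjusted p under 0.05, and 0 calls with limma-voom. Among genes named by the rule, which passes over predicted models, pseudogenes and microRNAs of smaller p, the log2 interactions were 1.55 (SE 0.28) for Krtcap2, a subunit of the oligosaccharyltransferase, and 2.08 (SE 0.50) for Ext2, a heparan sulfate polymerase. Gnrh1, which encodes gonadotropin-releasing hormone, had 2.46 (SE 0.65), Fbxw8 1.25 (SE 0.37) and Setmar 1.36 (SE 0.41). In the other direction stood Pou5f2 at -1.17, Pim1, a serine and threonine kinase, at -1.07, Ddit3, a stress-response transcription factor, at -0.998, the orphan nuclear receptor gene Nr2f6 at -0.77 and Med10 at -1.19. All had an adjusted p of 0.9996, and 0 of 25 lists were called. For Notch, contractile, cardiac, neural crest, white fat, erythroid, mesothelial and early stress genes camera placed the list lower where the median or the mean was positive. Notch1 had an interaction of -0.18 (SE 0.36).

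**Figure D4:**
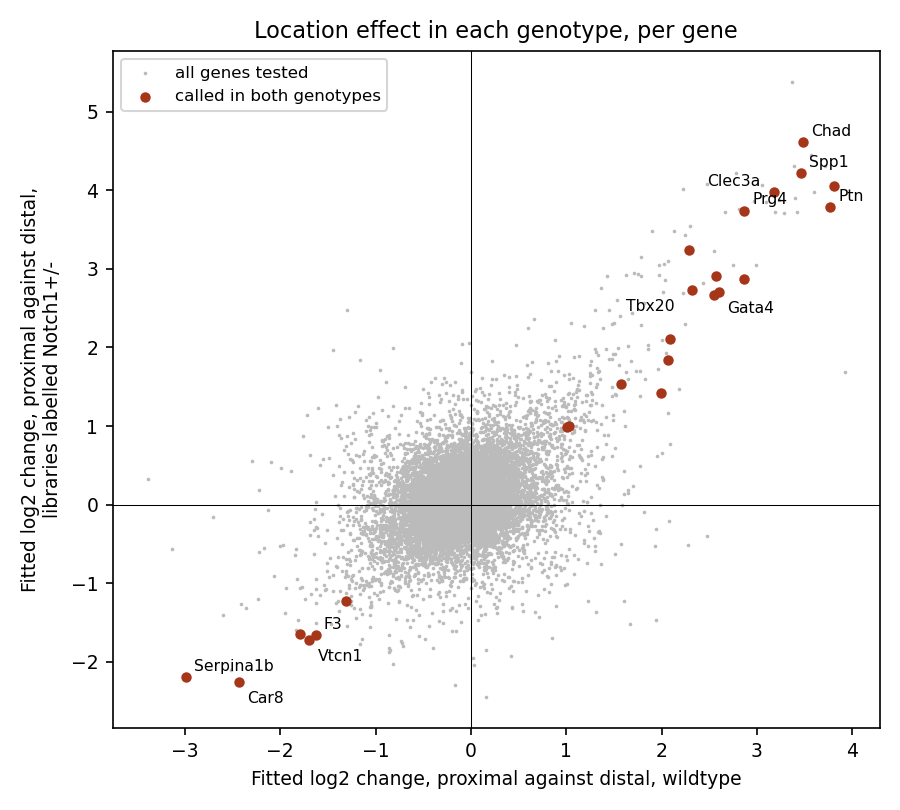
Fitted log2 change of proximal against distal tissue per gene, wildtype on the horizontal and libraries labelled Notch1+/- on the vertical axis, for 17297 genes in grey and the 24 genes called in both in red. The 18 shared genes that were higher lie at the upper right and the 6 that were lower at the lower left.

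In the proximal aorta no gene passed the test between genotypes. Limma called 0 of 17297 genes and limma-voom 0, while 561 genes had an unadjusted p under 0.05 where chance gives 865, and the smallest adjusted p was 0.540. Clec3a stood at 9.94 ± 1.22 RPKM in the libraries labelled Notch1+/- and 5.52 ± 1.07 in wildtype (SD, n = 3 each), a ratio of 1.80 at adjusted p 0.999. Other genes named by the rule, which passes over predicted models, pseudogenes and microRNAs of smaller p, had ratios of 2.28 for Rnf8, a ubiquitin ligase of the DNA damage response, 2.33 for Gkap1, 1.95 for the ribosomal protein gene Rps14 and 2.07 for Trappc2l. On the lower side wildtype stood 2.08-fold above for Tfip11, a splicing factor gene, 2.09-fold for Sardhos, 3.26-fold for Pole2, 2.95-fold for Gsto1 and 1.59-fold for Hs1bp3. All had an adjusted p of 0.999. Reads of Sardhos are uncertain, since 70.9% of its exon bases overlap an antisense gene, and Rps14 has near-identical processed copies.

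By list, 7 of 25 differed between genotypes in proximal tissue with camera's preset correlation, and 0 did with an estimated correlation, where adjusted p was 0.890 for each, or with fry. In the libraries labelled Notch1+/- 20 of 20 contractile genes (adjusted p 0.0157), 19 of 20 elastic fibre genes (0.00674), 25 of 27 collagen genes (0.0328) and 17 of 17 endothelial markers (0.0422) were fitted higher. Mitochondrially encoded genes were fitted lower in 13 of 13 cases (1.25e-05), white fat markers in 9 of 10 (0.0202) and erythroid markers in 4 of 5 (0.00538). Over all genes the median log2 difference was 0.11, and it was 0.00 after median-of-ratios scaling, under which contractile, collagen and white fat lists lost the call and 4 lists remained called. White fat also lost it under quantile normalization and protein-coding scaling, collagen under the latter and mitochondrially encoded genes under the former. The elastic fibre member Loxl1, a lysyl oxidase that cross-links elastin, had a ratio of 1.64 (log2 0.69, SE 0.28). Fibronectin, Fn1, had 1.57, the endothelial TGF-beta co-receptor Eng 1.59 and the tendon transcription factor Scx 2.20, all at adjusted p 0.999. All 7 list calls were lost without proximal library 1 labelled Notch1+/-, at adjusted p of 0.142 for contractile, 0.0992 for elastic fibre, 0.433 for collagen and 0.0992 for endothelial, 0.242 for white fat, 0.142 for erythroid and 0.0604 for mitochondrially encoded genes. Without wildtype proximal library 1 adjusted p was 0.346 for elastic fibre, 0.294 for collagen, 0.782 for endothelial and 0.147 for erythroid genes. Without wildtype proximal library 2 it was 0.269 for collagen, 0.0713 for endothelial and 0.0620 for white fat genes, and without wildtype proximal library 3 it was 0.316 for contractile and 0.279 for white fat genes. Without proximal library 3 labelled Notch1+/- it was 0.172 for contractile and 0.0709 for endothelial genes, and endothelial markers also lost the call without proximal library 2 (0.167) or distal library 3 (0.0702) of that label or wildtype distal library 1 (0.0574). Cardiac factors (median log2 difference 0.08), neural crest factors (0.08), heart muscle (0.25) and macrophage markers (0.05), interferon genes (0.15) and early stress genes (mean 0.06) were fitted higher. Camera placed these lists lower, none of them called.

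In the distal aorta no gene passed between genotypes either. Limma called 0 genes and limma-voom 0, with 524 at an unadjusted p under 0.05 and a smallest adjusted p of 0.483. Krtcap2 stood at 2.82 ± 0.362 RPKM in the libraries labelled Notch1+/- and 6.88 ± 0.959 in wildtype (SD, n = 3 each; log2 -1.15, SE 0.20, adjusted p 0.743). Wildtype also stood 2.68-fold above for Ext2, at least 6.64-fold for Ucp1, the uncoupling protein of brown fat, 1.91-fold for Ptcd2 and 2.79-fold for Enthd2, each at adjusted p 1. On the higher side were Nrip2 with a ratio of 3.22, the mediator subunit gene Med25 with 2.08, Plagl2 with 1.57 and Unk with 1.69, and Etv3l, which had 4 to 13 reads against 1 in each wildtype distal library. Contractile genes were the sole list called, with 19 of 20 fitted higher in the libraries labelled Notch1+/- (adjusted p 0.00331, and adjusted p = 0.939 with an estimated correlation). That call was lost without distal library 2 labelled Notch1+/- (0.113) or wildtype distal library 1 (0.470). Camera placed Notch, heritable aortopathy, renin-angiotensin, cardiac, neural crest, endothelial, glial and inflammatory genes higher although the median or the mean of each list was negative, none of them called (smallest adjusted p 0.4998). The genotype differences of the 2 locations correlated across genes at Pearson 0.0798 and Spearman 0.0687. They come from the same 6 mice, whose paired libraries had deviations from group means that correlated at 0.0731 to 0.216. Libraries of different mice that shared a number and a location correlated at -0.0265 to 0.249. The paired values can therefore not be read as an effect of the mouse alone.

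The samples were compared as wholes, since the series design reports clusters by location first and genotype second. Location held 16.9% of the variance over the 17297 genes, with a permutation p of 0.0312, the smallest that exchange of locations within mice can give. Genotype held 7.41%, with an exact permutation p of 0.9. Average linkage into 3 clusters gave the 6 proximal libraries, 5 distal libraries, and distal library 3 labelled Notch1+/- alone. Cut into 2 it set that library apart from the other 11. Median correlations were 0.931 within a group, 0.938 between genotypes at the same location and 0.921 between locations of the same genotype, and 0 pairs of libraries held identical values.

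**Figure D5:**
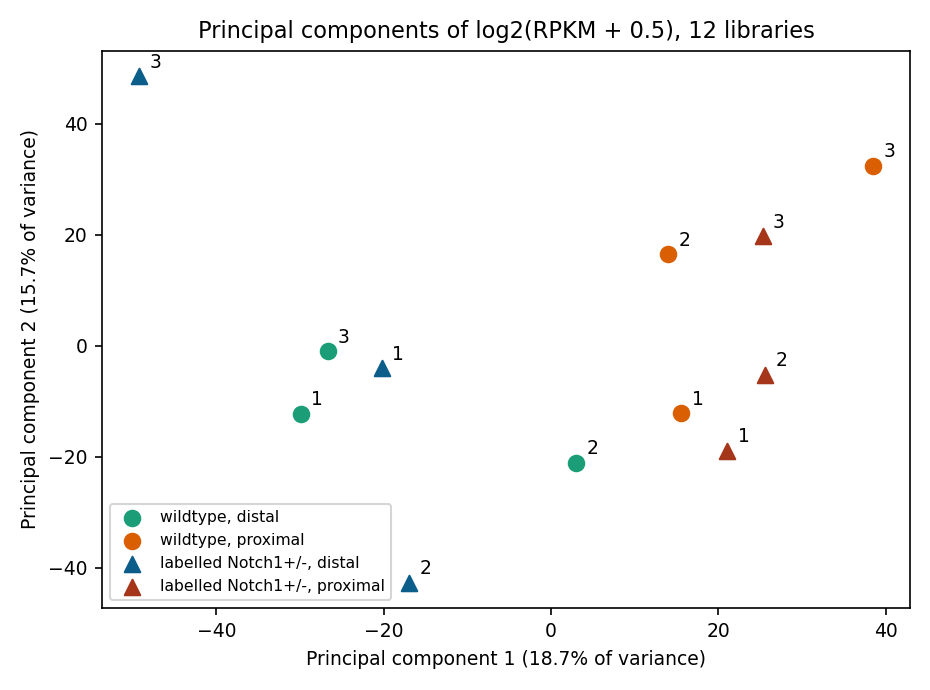
First and second principal components of log2(RPKM + 0.5) over 17297 genes, with 18.7% and 15.7% of the variance, for 12 libraries numbered by replicate. Proximal libraries lie to the right of all distal libraries, and genotypes (circles wildtype, triangles labelled Notch1+/-) intermingle.

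The authors' deposited table gave 145 genes with a false discovery rate under 0.05 in their 2-way test for location, 4 for genotype and 1 for the interaction. Of the 145 genes, 119 were among those tested with limma and 107 were among its 260 calls. The authors' Tukey comparisons in the deposited table gave 4 genes for location in wildtype, 9 for location in the libraries labelled Notch1+/-, 2 for genotype in proximal and 0 in distal tissue. For Notch1 the authors' deposited table gave wildtype to Notch1+/- folds of 0.579 in distal and 0.705 in proximal tissue, with a false discovery rate of 0.999 for genotype. The 4 genotype genes of the authors' deposited table were Snord98, Gm28651, Ddx28 and Gm22340, and Snord98 was the interaction gene; these were chosen after their values were seen.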

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

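The tests of scaling and of exchanged labels for Notch1, both tests of heart muscle, the comparison of hepatocyte markers with the fall of Serpina1 and the exchange within mice for lists were chosen after the result was seen. The tests of counting error, of shared reads and counts of hepatocyte markers for Serpina1, and of the other splits were chosen before.

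For 7 named genes every mouse of 1 genotype had a proximal to distal change opposite in sign to that of every mouse of the other. This difference was not tested by that comparison of signs, and the interaction had an adjusted p of 0.9996 for each of the 7. The change in the mice labelled Notch1+/- minus that in wildtype, on the log2 scale, was 0.45 for Eng, 2.08 for Ext2, 2.46 for Gnrh1 and 1.55 for Krtcap2. It was -0.77 for Nr2f6, -0.86 for Sardhos and -0.89 for Tfip11. Ext2, which elongates heparan sulfate, stood lower proximally in wildtype and higher in the mice labelled Notch1+/-, neither change called. Over the 17297 genes tested 320 (1.85%) met this criterion, where independent signs give 3.125%, and Krtcap2, Ext2, Gnrh1 and Nr2f6 were named for a small interaction p.

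Notch1 was higher in the libraries labelled Notch1+/- at both locations, by 0.47 (SE 0.18) on the log2 scale on average. That SE treats both libraries of a mouse as independent. With the mean of both locations per mouse, an exact permutation test gave p = 0.1, the smallest that 3 against 3 mice allow. A chance difference between mice therefore stays open. The tables argue against scaling, since the lowest of 4 other scalings gave 0.43. They also argue against counting error of independent reads, since 2433 against 1621 reads gave a ratio of 1.53 with an exact 95% Poisson interval of 1.43 to 1.63. Amplified reads are not independent molecules, so that interval does not cover the sampling of molecules. An exchange of some labels stays open: 0 libraries lay within the range of the other genotype at their location, but that separation is the pattern itself, and its gaps of 0.0621 RPKM in distal and 0.0706 in proximal tissue were smaller than the larger SD within groups (0.335 and 0.320). Open and untested are an exchange of all genotype labels, transcripts of the targeted allele counted as Notch1, and a biological difference. Within 10 megabases of Notch1, 10 of 247 genes (4.05%) in proximal and 8 (3.24%) in distal tissue had an unadjusted p under 0.05 between genotypes.

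The cardiomyocyte markers, including Myh6 and Tnnt2, stood higher in proximal libraries, and heart muscle attached to the tissue is a candidate explanation. Within groups the 22 markers varied together, with a mean residual correlation of 0.624 against a 95th percentile of 0.249 and a highest value of 0.425 over 10000 random lists matched on expression, as a varying share of heart muscle would give. Among the other lists tested the estimated correlation ran from -0.184 to 0.960. The white fat and mesothelial lists, at 0.716 each, exceeded 0.624, so varying together is not particular to heart muscle. For 88 other genes called higher, the median position between distal and proximal means was 0.502 in wildtype distal library 2 and 0.0728 in distal library 1 labelled Notch1+/-. In these libraries 44 and 6 of the 88 genes lay above the midpoint. The markers stood at 0.736 and 0.564, so the medians do not decide whether heart muscle brought the 88 genes as a set. With the heart muscle score as a covariate 252 of 260 genes had the same sign and the median size of change went from 1.18 (SE 0.214) to 0.979 (SE 0.362), so the calls ended mostly through a larger error, the score being tied to location at a correlation of 0.833. For the 88 genes as a set, a biological difference between the proximal and distal wall cannot be told apart from attached heart tissue, because the pair of libraries differed. Myh6 stood at 119 and 48.0 RPKM in that pair, but Tbx20 at 3.63 and 3.56 and Gata4 at 1.17 and 0.882. Wildtype proximal library 1, with Myh6 at 63.2 RPKM, held Tbx20 at 26.2 and Gata4 at 6.41. For Gata4 and Tbx20 these values argue against heart muscle as the source of the whole difference. Attached heart tissue without muscle is not covered.

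Serpina1a, Serpina1b, Serpina1c and Serpina1d, the alpha-1 antitrypsin genes, stood higher in distal tissue of wildtype mice and on average over genotypes. Reads shared between the paralogs may link their values, as 26.4% of the 50-base words of Serpina1b occur in the other 3, and 50.6% for Serpina1a, 71.1% for Serpina1c and 43.6% for Serpina1d, so the number of genes that differed is open. Averaged over genotypes, the tables argue against RNA from liver cells as the source of the whole difference. Of 3 measured hepatocyte markers 1 was fitted lower in proximal tissue. Apoh stood at 1.39 RPKM distally and 1.01 proximally, Ahsg at 0.724 and 3.04, and Serpina3k at 0.298 and 0.636. Without the filter their log2 changes of -0.35 (SE 0.20), 1.43 (SE 0.36) and 0.48 (SE 0.20) each lay over 2 SE above -1.26, -0.90 and -0.28. Those values stand for a fall with the smallest averaged Serpina1 ratio, 4.81. Within wildtype, where the smallest ratio was 7.85, the markers were not compared. Alb was not in the table. A biological difference between locations is open and was not tested.

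Other splits of the libraries were counted. For location averaged over genotypes 1 of 100 splits gave at least 260 genes, the real one, with 45 as the highest other. Within mice 1 of 32 exchanges did, with 1 as the highest other, so chance is unlikely to give that many genes. For the 13 lists the margin was narrow: 3 of 100 splits reached as many, the highest other giving 14, and within mice 1 of 32 exchanges did, the highest other giving 12. Both shares are under 0.05. Other splits still called up to 14 lists, and up to 12 within mice, so the number of lists alone cannot exclude chance. For the other contrasts the 10 splits of 3 against 3 libraries are too few for a share under 0.05. The real and highest other counts of genes were 41 and 1 for location in wildtype, 44 and 1 in the libraries labelled Notch1+/-, 0 and 1 for genotype in proximal, 0 and 1 in distal tissue and 0 and 0 for the interaction. For lists they were 11 and 8, 11 and 5, 7 and 7, 1 and 7, and 0 and 8 in the same order. For genotype in proximal tissue 2 splits reached 7 lists.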

How the results depend on the processing

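The fits with limma-voom, scaling to protein-coding genes, protein-coding genes alone, the heart muscle score and without the pair of distal heart libraries were chosen after the result was seen. The test of raw counts was not run, since no counts are held. Unless a reason is given, the cause was not tested.

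Location in wildtype gave 41 genes, and 5 with only the libraries compared, 21 with the mouse as a block, 81 with limma-voom, 71 with protein-coding genes alone (fewer genes tested) and 77 at adjusted p under 0.1. The libraries labelled Notch1+/- gave 44, and 29 with a pseudocount of 0.1, 321 with array weights, 95 with limma-voom, 80 with protein-coding genes alone and 84 at adjusted p under 0.1. The average gave 260, and 445 with array weights, 158 without the 2 distal libraries with heart muscle transcripts and 392 at adjusted p under 0.1. The heart muscle score left 2, 3 and 3 calls in these contrasts and, with the mouse as a block, 0, 0 and 0. Other alternatives, the libraries left out aside, stayed within 1.5 times. Genotype in distal tissue gave 0 genes, and 1 with array weights (Gm22547). The interaction and genotype in proximal tissue gave 0 in these alternatives.

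Leaving out 1 library gave 7 (wildtype distal 3) to 44 genes for location in wildtype, 14 (Notch1+/- proximal 2) to 51 in the libraries labelled Notch1+/- and 141 (Notch1+/- proximal 2) to 226 on average. It gave 0 to 1 for genotype in proximal tissue (Hmgn2-ps1 without wildtype proximal 1), 0 to 1 in distal tissue (Snord2 without Notch1+/- distal 2) and 0 to 0 for the interaction. These 3 single genes were chosen after their values were seen. The log2 difference of Notch1 ranged from 0.27 to 0.49 in proximal and 0.37 to 0.69 in distal tissue. Lists called ranged from 8 to 13, 10 to 13, 9 to 16, 0 (Notch1+/- proximal 1) to 7, 1 to 4 and 0 to 2 in the order of contrasts.

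Lists called numbered 11, 11, 13, 7 and 1 for location in wildtype, labelled Notch1+/-, averaged, and genotype in proximal and distal tissue. An estimated correlation gave 3, 1, 3, 0 and 0 and fry 3, 4, 5, 0 and 0. The heart muscle score gave 7, 6 and 7 for location, and 7 with the block in the libraries labelled Notch1+/-. Median-of-ratios scaling gave 4 for genotype in proximal tissue. For genotype in distal tissue 2 lists were called after rescaling to a constant sum, without a filter, with a filter at 0.1 RPKM, with a random mouse effect, with limma-voom, without the heart pair and with the heart muscle score. The interaction gave 0 lists, and 1 without the heart pair. Complete linkage parted 12 libraries by location and average linkage 7.

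Directions reversed only with the heart muscle score. Myh6, a member of the score by construction, went to -0.40 on average and to -0.080 with the block. Adjusted p of lists with reversed direction were, for mesothelial markers, 0.914 in wildtype, 0.858 in the libraries labelled Notch1+/- and 0.930 averaged, and with the block 0.0448, 0.00507 and 0.00749. For macrophage markers with the block they were 0.120, 0.125 and 0.0806. Brown fat markers had 0.492 and 0.0542 with the block in the libraries labelled Notch1+/-, and 0.230 and 0.0161 averaged. Neural crest factors had 0.930 averaged, and endothelial markers 0.859 with the block in the libraries labelled Notch1+/-.

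Over 93 called results of named genes 2204 of 2641 values kept direction and call, 435 lost the call and 2 reversed. Over 76 results not called 2098 of 2114 values stayed so and 16 passed. Over 43 list calls 986 of 1189 values kept the call, 188 lost it and 15 reversed. Of the 41, 44 and 260 calls 39, 42 and 243 were shared with limma-voom, 19, 25 and 184 with the mouse as a block, and 26, 28 and 137 without the 2 distal libraries with heart muscle transcripts. Across genotypes 9 of 12 libraries correlated best with the library of their own number, among 3 candidates at their location. Library identifiers run in sets of 4 by number, so a shared processing set is open. With the number as a block the genotype contrasts gave 0 and 0 genes and 7 and 1 lists. Depth limits low genes: per the file headers 10 reads stand for 0.136 to 0.189 RPKM, and 9.78% of values lay at the floor. The reads behind a value vary with gene length. In distal library 3 labelled Notch1+/- the floor stands for 2 reads of Clec3a and 15 of Corin.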

Other observations

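Both groups of genes and the single gene below were chosen after their values were seen, and no explanation was tested for them.

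Several genes of lymphatic endothelium stood higher in the proximal aorta, averaged over genotypes (n = 6 each). Flt4, the receptor for VEGF-C, was 5.38-fold higher (log2 1.90, SE 0.21, limma adjusted p 0.00072). Prox1, the transcription factor that specifies lymphatic endothelium, was at least 5.96-fold and Mmrn1, a multimerin gene, at least 6.46-fold higher. The lymphatic chemokine genes Ccl21a and Ccl21b, near-identical copies whose reads cannot be assigned with certainty, were 8.42-fold and 10.8-fold higher. Lyve1, a hyaluronan receptor of lymphatic endothelium and macrophages, had a log2 difference of 0.65 at adjusted p 0.390 and was not called.

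The 4 genes of MHC class II antigen presentation named here stood higher in the proximal aorta as well. Cd74, the invariant chain, was 5.60-fold higher, at 42.2 ± 10.5 against 7.53 ± 5.35 RPKM (SD, n = 6 each, limma adjusted p 0.00206). H2-Aa had a log2 difference of 1.95, and H2-Ab1 was 4.21-fold and H2-Eb1 at least 4.29-fold higher.

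Scgb1a1, the secretoglobin of airway club cells, varied widely among libraries of a group. It stood at 99.8, 19.5 and 161 RPKM in wildtype distal libraries 1, 2 and 3 and at 145, 0.241 and 47.3 RPKM in the wildtype proximal ones. In the libraries labelled Notch1+/- it lay at 3.84, 1.55 and the floor in distal and at 1.08, the floor and 14.3 RPKM in proximal tissue. It was the sole measured epithelial marker, so adjustment over the list alone is no adjustment. Between genotypes in distal tissue its unadjusted limma p was 0.00828 (log2 -5.25, SE 1.67), and it did not pass over all genes.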
